A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

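Poly(A) RNA was sequenced from haploid budding yeast (Saccharomyces cerevisiae) of the laboratory strain BY4741 and from a knockout of TRM2 (YKR056W), the methyltransferase that makes 5-methyluridine at position 54 of tRNAs. Each genotype was grown in rich medium without or with 50 µg/mL hygromycin B, an aminoglycoside that blocks the translocation step of translation elongation. The 8 libraries fell into 4 groups of 2, which the series describes as biological duplicates, and groups were taken from the sample labels. Per the labels' protocols, Geneticin was present at 200 µg/mL in the knockout cultures, and the wild-type cultures are not said to have had it. Below, without drug and untreated mean without hygromycin B. The same protocols give a lower harvest density for hygromycin B cultures than the general one, and they mention cycloheximide, for which no library was analysed here. RNA was extracted with hot phenol, depleted of small RNA, selected with oligo-dT beads and depleted of rRNA with hybridisation probes, per the labels' protocols.

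The deposited table held 1 FPKM value (fragments normalised to transcript length and to the mapped fragments of the library) for each of 7127 features in each of the 8 libraries, made by the authors from their reads. Per the submitters' processing notes, the tools were cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a and RSEM 1.3.3. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. Because the strand setting was not given, a gene and an overlapping gene on the other strand cannot be separated. RSEM divides reads between near-identical genes, so values of such copies, among them CUP1-1 and CUP1-2, are uncertain. Exact zeros in such a table can be failed estimates, and genes with a zero are given by library, with no fold. Features were matched by identifier to the RefSeq table of assembly R64 for names and gene lengths, which succeeded for 6047 of them. Neighbours and overlaps came from the gene coordinates of that assembly. No column of the table was left unused.

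The FPKM values summed to between 1171274 and 1654849 per library. The 22 features with ribosomal DNA names made up 2.01% to 19.3% of the sum, called the ribosomal DNA share, which differed within groups. Features under other names are not in it, among them YLR154W-C, the highest feature of untreated wild-type library 1 and of every knockout library. FPKM were divided by a scale factor per library, the median ratio of a library's values to the geometric mean over libraries, and the factors ran from 0.611 to 1.44. These values are called normalised FPKM. Read depth was unknown, since the table holds no counts. The low values were searched for whole multiples of what 1 read would be worth at each gene's length, and the best periodicity of a library was 0.206 to 0.319, which between 0 and 9 of 10 shuffles of gene length matched or exceeded, depending on the library. No counting interval or detection limit was therefore computed.

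Genes with a mean FPKM of at least 1 over the 8 libraries were tested, 6439 in all. Log2(normalised FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean-variance trend). All 8 libraries entered 1 fit with 1 mean per group, which left 4 residual degrees of freedom and 6.39 after moderation. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and an adjusted p under 0.05 is called a change. Every fold change is on the log2(normalised FPKM + 1) scale, which understates changes of low genes. The 5 comparisons were knockout against wild type without drug, hygromycin B against no drug in wild type, the same in the knockout, knockout against wild type with hygromycin B, and the genotype by hygromycin B interaction. All changes are relative to the other genes of a library, because the table holds no measure of total RNA per cell.

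There were 27 gene lists tested with camera in limma at the preset inter-gene correlation of 0.01, among lists with at least 5 tested members, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera asks whether a list moved relative to all other genes. The test was repeated with an inter-gene correlation estimated for each list. In that form camera also takes its degrees of freedom from the residuals, 4 here, and not from the number of genes. A further list, of genes deleted or disrupted in BY4741, had too few tested members and is given by gene.

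The comparisons, tests, gene lists, processing alternatives and the rule for named genes were fixed before the data were examined. The rule named TRM2 first. It then took the 10 highest and 10 lowest log2 changes among genes past the threshold with a mean of at least 10 normalised FPKM in the higher group and no overlap of replicates between the groups. For the interaction it took 5 in each direction. It added up to 4 members with the smallest p from each gene list, the genes next to TRM2, and the genes deleted or disrupted in BY4741. Genes outside the rule appear only in the closing section, in lists written after the results were seen.

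The fits were tested on simulated values drawn around each gene's mean over the libraries with its spread within groups, with 100 genes changed 1.5-fold, 100 changed 2-fold and the proteasome list shifted by 0.4 on the log2 scale. The changed genes had means above about 10 normalised FPKM and lay outside the lists. For the knockout against wild type without drug, 77 of the 1.5-fold and 93 of the 2-fold genes were recovered among 6401 genes, with 14 false calls. For hygromycin B in wild type the numbers were 78 and 90 among 6401 genes, with 8 false calls. For hygromycin B in the knockout they were 77 and 88 among 6396, with 6 false calls. For the knockout against wild type in hygromycin B they were 79 and 88 among 6405, with 8 false calls. For the interaction they were 66 and 82 among 6399, with 12 false calls. The shifted list was called in each simulation with the preset correlation, and 0 other lists were. With an estimated correlation the shifted list had a camera adjusted p under 0.05 in each simulation too. Genes were drawn independently of each other, so the simulation does not test the estimated correlation. It also changed few genes around means shared by all groups, whereas 43% to 78.7% of genes were called in the data. The simulation therefore gives no error rate for changes that wide and does not test the scaling there.

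Alternatives were FPKM as deposited, scaling of each library to the same sum (TPM), quantile normalisation, pseudocounts of 0.1 and 5, a mean of at least 10 or no filter, no variance trend, only the 4 libraries of a comparison, the replicate number as a block, a minimum 2-fold change, and each library left out in turn. A fit with the ribosomal DNA share as a covariate, and one without any feature listed at 0 in a library, were added after seeing the data. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.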

Results

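The data were 8 poly(A) RNA-seq libraries of budding yeast, 2 for each of 4 groups: wild type and trm2 knockout, each without and with 50 µg/mL hygromycin B. The knockout cultures also had 200 µg/mL Geneticin, per the labels' protocols. Effects of the knockout and of Geneticin therefore cannot be told apart in any comparison of the genotypes, including those called without drug. The series asks how the tRNA methylation made by Trm2 bears on gene expression when translation elongation is unimpeded and when it is inhibited. Between 6422 and 6513 features were above 0 per library, and 6439 genes were tested. Pearson correlations of log2 values between the 2 libraries of a group were 0.984 to 0.989, and their median absolute log2 difference was 0.057 to 0.13. The first principal component held 73% of the variance. The wild-type hygromycin B libraries lay at 72.0 and 64.5 on it, and the other 6 libraries between −34 and −15.4. Features with ribosomal DNA names made up 15.8% and 2.01% of the FPKM sum in untreated wild type, 2.68% and 2.39% in treated wild type, 19.3% and 5.36% in the untreated knockout, and 3.75% and 12.2% in the treated knockout.

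TRM2 (YKR056W) was at 116 and 122 normalised FPKM in the untreated wild-type libraries and at 158 and 153 in the treated ones, and it was listed at 0 in all 4 knockout libraries. In wild type TRM2 rose 1.3-fold with hygromycin B (log2 0.38 ± 0.075 SE, limma adjusted p = 0.00317). That call ended without untreated wild-type library 1 (log2 0.34, adjusted p = 0.0515) and with FPKM as deposited (log2 0.99, adjusted p = 0.0541). The genes next to TRM2 are RHO4 and RPS21A, whose knockout to wild-type log2 differences without drug were 0.27 ± 0.06 (SE, adjusted p = 0.0124) and 0.30 ± 0.08 (adjusted p = 0.0287). Both differences turned with the scaling, RHO4 to −0.03 with FPKM as deposited and RPS21A to −0.05 with quantile normalisation, and neither passed without untreated knockout library 2 (adjusted p = 0.0714 and 0.136). Of the genes deleted in BY4741, LEU2, URA3 and MET17 were listed at 0 in all 8 libraries. HIS3, which is deleted in part, had 34.4 to 54.1 normalised FPKM.

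Without drug, FIT2, a cell wall mannoprotein that retains siderophore iron, was 12.1-fold higher in knockout than in wild-type cells, at 3348 ± 891 against 271 ± 21.8 normalised FPKM (SD, n = 2; log2 3.60 ± 0.23 SE, adjusted p = 0.000197). SIT1, a siderophore transporter, rose 3.6-fold, from 61.6 ± 3.43 to 224 ± 14.1. AZR1, a drug and azole transporter of the plasma membrane, rose 8.39-fold (log2 3.07 ± 0.065, adjusted p = 3.7e-06), and the uncharacterised genes YLL056C and YLR046C rose 9.07-fold and 7.44-fold. ADE17, an enzyme of purine synthesis, fell by 2.91 on the log2 scale, from 567 ± 29.8 to 74.4 ± 0.74 normalised FPKM (adjusted p = 6.44e-06). TDH1, a glyceraldehyde-3-phosphate dehydrogenase, fell from 296 ± 45.9 to 52.3 ± 1.2, and RGI1, a gene of energy metabolism under respiratory growth, fell from 383 ± 115 to 59.9 ± 0.785.

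Of the 24 tested members of the iron regulon (Aft1/2-type), 19 rose and 1 fell over all genes, and the same numbers passed when adjusted over the list alone. Their median was 0.93 and FET3, the iron-oxidising oxidase of high-affinity uptake, rose from 185 ± 4.63 to 490 ± 18.7 normalised FPKM (camera adjusted p = 1.14e-08). The iron call had an adjusted p = 0.433 with an estimated correlation. In the general stress response (Msn2/4-type), 46 of 60 members fell and 2 rose, or 47 and 2 adjusted over the list alone, with a median of −0.70. Its camera adjusted p was 8.51e-13, and adjusted p = 0.433 with an estimated correlation. HSP26, a small heat shock protein, fell from 52.7 ± 6.89 to 15.9 ± 1.23, and GLG1, which primes glycogen synthesis, from 66.8 ± 8.52 to 17.4 ± 0.35. Of 66 genes for mitochondrial ribosomal proteins 44 fell and 1 rose, or 45 and 1 adjusted over the list alone, among them MRPL38 at log2 −0.63. The median was −0.31 (camera adjusted p = 1.66e-10, and adjusted p = 0.433 with an estimated correlation). In the phosphate regulon (Pho4-type), 12 of 19 members fell and 0 rose, or 13 and 0 adjusted over the list alone (median −0.51, camera adjusted p = 1.42e-06, and adjusted p = 0.135 with an estimated correlation). PHO84, the high-affinity phosphate transporter, fell from 188 ± 4.45 to 77.9 ± 0.634 normalised FPKM. These 4 list calls held under each scaling and without each single library. As single genes FET3 (adjusted p = 0.297) and MRPL38 (adjusted p = 0.435) did not pass with FPKM as deposited.

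Genes for cytosolic ribosomal proteins were slightly higher in the knockout without drug, a call that ended with quantile normalisation. Of 97 members 60 rose and 0 fell, or 72 and 0 adjusted over the list alone, and RPS28B rose most clearly, by log2 1.23 ± 0.16 (SE, adjusted p = 0.00208). The median of the list was 0.30 (camera adjusted p = 2.26e-10, and adjusted p = 0.494 with an estimated correlation), but 0.02 with quantile normalisation (camera adjusted p = 0.675). It was 0.00 with FPKM as deposited and 0.07 with TPM for these cytosolic ribosomal proteins, where the list was still called. RPS28B did not pass with FPKM as deposited (adjusted p = 0.52). Of 22 aminoacyl-tRNA synthetases 14 rose, or 19 adjusted over the list alone, with a median of 0.26 that was −0.04 with FPKM as deposited. Of 61 genes for tRNA modification and maturation 26 rose and 3 fell, equally adjusted over the list alone, with a median of 0.15 that was −0.15 with FPKM as deposited and −0.08 with TPM. Of 27 ergosterol biosynthesis genes 16 rose and 0 fell, equally adjusted over the list alone, with a median of 0.22 that was −0.08 with FPKM as deposited and −0.01 with TPM. Of 30 translation initiation factors 11 rose and 0 fell, equally adjusted over the list alone, with a median of 0.16 that was −0.13 with FPKM as deposited and −0.07 with TPM. Of 38 genes for ribosome quality control and mRNA surveillance 16 rose and 4 fell, or 17 and 4 adjusted over the list alone, with a median of 0.12 that was −0.17 with FPKM as deposited and −0.10 with TPM. The camera adjusted p values of these 5 lists were 8.39e-06, 0.000926, 0.000185, 0.0133 and 0.0189, and adjusted p = 0.433, 0.494, 0.433, 0.603 and 0.494 with an estimated correlation. The calls other than ergosterol biosynthesis ended with FPKM as deposited (adjusted p = 0.0609 to 0.222). Those of translation initiation factors and of ribosome quality control and mRNA surveillance also ended under both other scalings. Their camera adjusted p values were 0.154 and 0.137 with TPM, and 0.285 and 0.0643 with quantile normalisation.

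The other 4 lists called without drug were lower in the knockout by small amounts. Of 40 proteasome genes 13 fell and 2 rose, or 13 and 1 adjusted over the list alone, with a median of −0.09. Of 40 glucose-repressed genes 15 fell and 6 rose, equally adjusted over the list alone, with a median of −0.17, and the hexose transporter gene HXT4 fell from 709 ± 75.8 to 185 ± 16.2 normalised FPKM. Of 37 genes for methionine and sulfate assimilation 10 fell and 2 rose, or 9 and 2 adjusted over the list alone, with a median of −0.14. Of 22 sporulation and meiosis genes 8 fell and 2 rose, or 9 and 2 adjusted over the list alone, with a median of −0.32. Their camera adjusted p values were 0.0134, 0.0189, 0.0324 and 0.0492, and adjusted p = 0.494, 0.494, 0.494 and 0.433 with an estimated correlation. Without untreated knockout library 1 all 4 calls ended (adjusted p = 0.0627, 0.0627, 0.0941 and 0.0627), as did that of ribosome quality control and mRNA surveillance (adjusted p = 0.0627). The calls for methionine and sulfate assimilation and for sporulation and meiosis genes also ended without untreated wild-type library 1 (adjusted p = 0.0532 and 0.0765), and the latter without each of 3 further libraries (adjusted p = 0.0539 to 0.0688). Each of the 4 calls ended under at least 1 other scaling as well.

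In all, 2771 of 6439 genes passed for knockout against wild type without drug, 1491 higher and 1280 lower, and 225 of them changed at least 2-fold, 55 higher and 170 lower. With FPKM as deposited the median of all genes was at −0.26, 163 genes passed and 14.1% of them were higher, against 53.8% with the scale factors. With TPM the median was at −0.19, 1032 genes passed and 11.4% of them were higher.

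With hygromycin B the wild-type transcriptome differed widely from that without drug. PUT1, the proline oxidase of the mitochondrion, rose 189-fold, from 5.92 ± 0.49 to 1309 ± 73.8 normalised FPKM (SD, n = 2; log2 7.57 ± 0.13 SE, limma adjusted p = 3.9e-07). NRG1, a repressor of glucose-repressed genes, rose 90.1-fold and HSP12, a membrane-associated stress protein, rose 76.7-fold, from 85.5 ± 25 to 6603 ± 1720. CUP1-1 and CUP1-2, the copper metallothionein genes, had identical values and rose 54.5-fold, from 373 ± 45.6 to 20360 ± 1710, with reads that cannot be separated between the copies and the overlapping RUF5 copies. The stress gene DDR2 was at 5.67 and 11 in the untreated libraries and at 1025 and 780 in the treated ones. SRL1 and CIS3, mannoproteins of the cell wall, fell by 5.14 and 5.09 on the log2 scale, from 752 ± 21.7 to 20.9 ± 7.02 and from 853 ± 20.5 to 24.3 ± 5.14. The glycolytic and fermentative genes ENO2 and ADH1, among the most abundant transcripts of untreated cells, fell from 6093 ± 177 to 239 ± 64.6 and from 6949 ± 127 to 289 ± 82.6.

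Glycolysis and fermentation had 20 of 21 members lower and 1 higher with hygromycin B in wild type, in the count over all genes and adjusted over the list alone (median −2.78, camera adjusted p = 1.42e-06, and adjusted p = 0.517 with an estimated correlation). The member that rose was PDC5, a minor pyruvate decarboxylase, from 12 ± 0.466 to 348 ± 47. Of the 97 genes for cytosolic ribosomal proteins 86 fell and 4 rose, or 86 and 5 adjusted over the list alone, with a median of −0.90 (camera adjusted p = 2.74e-10, and adjusted p = 0.517 with an estimated correlation). With quantile normalisation the cytosolic ribosomal proteins had a median of −0.19 and an adjusted p of 0.062 by camera. Of 22 aminoacyl-tRNA synthetases 21 fell and 0 rose, and of 30 translation initiation factors 25 fell and 0 rose. Of 18 translation elongation and termination factors 15 fell and 3 rose, among the latter ANB1, the hypoxic form of eIF5A. These numbers were equal adjusted over the list alone. Their medians were −1.14, −0.69 and −1.05, with camera adjusted p = 1.06e-06, 1.78e-05 and 0.00311, and adjusted p = 0.392, 0.517 and 0.517 with an estimated correlation. TEF4, a subunit of elongation factor eEF1B, fell from 1318 ± 16.4 to 182 ± 30.5, and GUS1, the glutamyl-tRNA synthetase, from 405 ± 6.92 to 126 ± 9.8.

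Of the 40 proteasome genes, 35 fell and 2 rose with hygromycin B in wild type, equally adjusted over the list alone. The median was −0.88 (camera adjusted p = 1.42e-07, and adjusted p = 0.392 with an estimated correlation). ECM29, a proteasome adaptor, fell from 25 ± 0.393 to 3.36 ± 0.376. All 10 histone genes fell, over all genes and adjusted over the list alone (median −1.71, camera adjusted p = 0.000116, and adjusted p = 0.517 with an estimated correlation), HTB2 from 816 ± 21.7 to 138 ± 4.54. Of 29 genes of the unfolded protein response of the endoplasmic reticulum 22 fell and 3 rose, among them PMT1, a protein mannosyltransferase, from 205 ± 5.19 to 38.2 ± 4.21. Of 27 ergosterol biosynthesis genes 20 fell and 4 rose. Of 15 a-cell and haploid genes 13 fell and 2 rose, and of 45 genes for cell wall integrity and cell wall 28 fell and 12 rose. These numbers were equal adjusted over the list alone. The 4 medians were −0.76, −0.61, −1.28 and −1.06, with camera adjusted p = 0.000222, 0.00105, 0.000442 and 0.0162, and adjusted p = 0.392, 0.45, 0.392 and 0.788 with an estimated correlation.

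The lists that rose with hygromycin B in wild type were stress and nutrient genes. In the general stress response (Msn2/4-type), 40 of 60 members rose and 12 fell, equally adjusted over the list alone (median 0.75, camera adjusted p = 0.00197, and adjusted p = 0.759 with an estimated correlation). HSP26 rose from 52.7 ± 6.89 to 427 ± 5.68. Of the 24 genes of the iron regulon (Aft1/2-type), 18 rose and 2 fell, or 20 and 2 adjusted over the list alone (median 0.90, camera adjusted p = 0.000428, and adjusted p = 0.517 with an estimated correlation). TIS11, which destabilises mRNAs of iron-using proteins, rose from 30.3 ± 2.9 to 244 ± 11.4, whereas FRE1, a surface reductase of copper and iron, fell from 165 ± 11.7 to 28.7 ± 0.665. Methionine and sulfate assimilation had 22 of 37 members higher and 10 lower equally adjusted over the list alone (median 0.47, camera adjusted p = 0.0301, and adjusted p = 0.517 with an estimated correlation). That call ended without treated wild-type library 2 (adjusted p = 0.0544). Of 40 glucose-repressed genes 24 rose and 10 fell, or 25 and 10 adjusted over the list alone (median 0.76, camera adjusted p = 0.0301, and adjusted p = 0.517 with an estimated correlation). That call ended under each other scaling (adjusted p = 0.0682 to 0.119) and among genes with a mean of at least 10 FPKM (adjusted p = 0.201).

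In wild type 5070 genes passed with hygromycin B, 2599 higher and 2471 lower, and 1885 changed at least 2-fold, 946 higher and 939 lower. With FPKM as deposited the median of all genes was at 0.62, 2550 genes passed and 85.6% of them were higher, against 51.3% with the scale factors. With TPM the median was at 0.40 and 72% were higher. Per the labels' protocols treated cultures were harvested at an OD600 of 0.4 and untreated ones at 0.6 to 0.8, so effects of the drug and of harvest density cannot be told apart, in wild type or in the knockout.

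In the knockout, hygromycin B gave smaller changes. HSP12 rose 26.9-fold, from 57.8 ± 13.4 to 1567 ± 219 normalised FPKM (SD, n = 2; log2 4.75 ± 0.28 SE, limma adjusted p = 0.000205), and HOR7, another stress-induced gene, rose 5.18-fold, from 206 ± 10.2 to 1074 ± 95. GCV1 and GCV2, subunits of the glycine decarboxylase complex, rose 6.29-fold and 5.26-fold. NRG1 rose 5.2-fold. BSC1 and PRM7, which lie close together in the genome, fell by 4.34 and 4.07 on the log2 scale, from 96.4 ± 16.2 to 3.91 ± 1.68 and from 75.1 ± 12 to 3.53 ± 0.479. The hexose transporter genes HXT2 and HXT3 fell from 396 ± 44.8 to 61.5 ± 1.27 and from 1539 ± 177 to 323 ± 39.6.

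In the general stress response (Msn2/4-type) 40 of 60 members rose in the knockout and 1 fell, or 41 and 1 adjusted over the list alone (median 0.85, camera adjusted p = 1.17e-11, and adjusted p = 0.589 with an estimated correlation). Of 21 genes of glycolysis and fermentation 18 fell and 2 rose, and of 18 translation elongation and termination factors 14 fell and 0 rose. Of 24 genes of the iron regulon (Aft1/2-type) 16 rose and 1 fell. These numbers were equal adjusted over the list alone. Of 22 aminoacyl-tRNA synthetases 20 fell, or 21 adjusted over the list alone. These 4 medians were −0.87, −0.50, 0.45 and −0.44, with camera adjusted p = 2.41e-06, 9.14e-05, 6.24e-06 and 7.33e-09, and adjusted p = 0.589, 0.589, 0.589 and 0.543 with an estimated correlation. ADH1 fell from 8526 ± 873 to 3613 ± 127 and TIS11 rose from 90.1 ± 9.83 to 203 ± 17.9. All 5 of these list calls held under each scaling.

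The remaining list calls in the knockout were small, and the direction of several turned with the scaling. Of 152 ribosome biogenesis genes 92 fell and 1 rose, or 95 and 2 adjusted over the list alone, with a median of −0.29 that was 0.12 with FPKM as deposited and 0.01 with TPM (camera adjusted p = 1.7e-13, and adjusted p = 0.589 with an estimated correlation). NSR1, a nucleolar protein of rRNA processing, fell from 1039 ± 132 to 431 ± 11.1. Of the cytosolic ribosomal proteins 44 fell and 2 rose, also adjusted over the list alone, with a median of −0.26 that was 0.14 with FPKM as deposited and 0.04 with TPM and with quantile normalisation (camera adjusted p = 2.41e-06, and adjusted p = 0.589 with an estimated correlation). NSR1 did not pass with FPKM as deposited (adjusted p = 0.537). Of 27 ergosterol biosynthesis genes 17 fell and 2 rose, or 19 and 2 adjusted over the list alone, with a median of −0.33 that was 0.08 with FPKM as deposited. Of 30 translation initiation factors 17 fell and 1 rose, or 17 and 2 adjusted over the list alone, with a median of −0.23 that was 0.17 with FPKM as deposited and 0.07 with TPM. Their camera adjusted p values were 6.12e-05 and 0.000793, and adjusted p = 0.543 and 0.589 with an estimated correlation. With quantile normalisation the call for translation initiation factors ended (adjusted p = 0.2), as did that of the cytosolic ribosomal proteins (adjusted p = 0.235).

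A further 4 lists were lower in the treated knockout with medians that turned to 0.20 to 0.22 with FPKM as deposited, where their calls ended (adjusted p = 0.111 to 0.198). With TPM these medians were 0.09 to 0.12. All of these calls but that of mitochondrial respiration and the TCA cycle (camera adjusted p = 0.0487) ended there too (camera adjusted p = 0.0689 to 0.135). Of 52 nuclear genes for mitochondrial respiration and the TCA cycle 19 fell and 1 rose (median −0.18), and of 66 mitochondrial ribosomal proteins 25 fell and 3 rose (median −0.19). Of 29 genes of the unfolded protein response of the endoplasmic reticulum 13 fell and 1 rose (median −0.21), and of 61 genes for tRNA modification and maturation 28 fell and 8 rose (median −0.20). Adjusted over the list alone 31 fell in the last list and 8 rose, and the other numbers were equal. Their camera adjusted p values were 0.00161, 0.00459, 0.00459 and 0.00554, and adjusted p = 0.589, 0.589, 0.543 and 0.589 with an estimated correlation.

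Of 37 heat shock factor and chaperone genes 16 rose and 8 fell in the knockout with hygromycin B, or 18 and 9 adjusted over the list alone (median 0.17), and BTN2, which sorts misfolded proteins, rose by log2 1.55. Of 38 genes for ribosome quality control and mRNA surveillance 16 rose and 4 fell, or 16 and 6 adjusted over the list alone (median 0.12). Of 40 proteasome genes 13 rose and 1 fell, equally adjusted over the list alone (median 0.07). Their camera adjusted p values were 0.0134, 0.017 and 0.0435, each with an adjusted p = 0.589 with an estimated correlation. The first call ended without untreated knockout library 1 (adjusted p = 0.0547). The second ended with FPKM as deposited (adjusted p = 0.128) and with TPM (adjusted p = 0.0541). The proteasome call ended with FPKM as deposited (adjusted p = 0.334), with TPM (adjusted p = 0.232) and without each of 6 of the 8 libraries (adjusted p = 0.0501 to 0.171).

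In the knockout 2787 genes passed with hygromycin B, 1343 higher and 1444 lower, and 148 changed at least 2-fold, 73 higher and 75 lower. With FPKM as deposited the median of all genes was at 0.36, and 82 genes rose and 23 fell, so that 78.1% were higher, against 48.2% with the scale factors. With TPM the median was at 0.26 and 1513 genes passed, 90.5% of them higher.

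**Figure D1:**
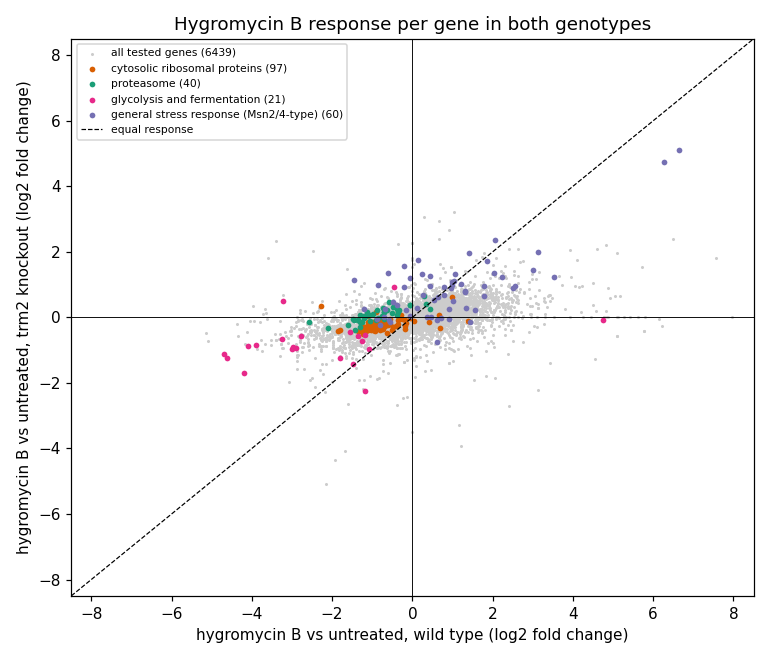
Log2 fold change with hygromycin B for each of 6439 tested genes, in wild type (horizontal axis) and in the trm2 knockout (vertical axis), each from 2 treated and 2 untreated libraries, with 4 gene lists coloured and the dashed line marking an equal response. The total least squares slope through all genes is 0.226. The axes are relative to the median-of-ratios scaling, and the knockout median of the cytosolic ribosomal proteins, −0.26, is 0.14 with FPKM as deposited.

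The difference between the genotypes' responses was tested as an interaction, and 4153 genes passed, 1971 with a higher and 2182 with a lower response in the knockout, of which 1302 differed at least 2-fold. A higher response means a more positive log2 change, which includes a smaller fall, and a lower response includes a smaller rise. Histones, for example, had medians of −1.71 in wild type and −0.14 in the knockout, which is a higher but weaker response. The median absolute log2 change with hygromycin B was 0.652 in wild type and 0.236 in the knockout. Across 6439 genes, which are not independent replicates, the 2 responses had a Pearson correlation of 0.488, a Spearman correlation of 0.564 and a total least squares slope of 0.226, with no library shared between them. Genes that rose in both numbered 1052, against 542 for independent lists, and genes that fell in both numbered 1050, against 554. Genes that rose in wild type and fell in the knockout numbered 197, against 583, and the opposite 129, against 515.

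The proteasome list had the smallest camera p of the interaction, with 37 of 40 members having a higher response in the knockout and 0 a lower one, equally adjusted over the list alone (median 1.02, adjusted p = 1.28e-11, and adjusted p = 0.26 with an estimated correlation). Of the cytosolic ribosomal proteins 77 of 97 were higher and 4 lower, or 78 and 4 adjusted over the list alone (median 0.64, camera adjusted p = 1.19e-08, and adjusted p = 0.64 with an estimated correlation). All 10 histone genes, 13 of 15 a-cell and haploid genes (2 lower) and 17 of 21 genes of glycolysis and fermentation (2 lower) had a higher response in the knockout. So did 21 of 30 translation initiation factors (0 lower) and 21 of 29 genes of the unfolded protein response of the endoplasmic reticulum (2 lower). These numbers were equal adjusted over the list alone. The 5 medians were 1.34, 1.25, 1.96, 0.41 and 0.53, with camera adjusted p = 2.78e-05, 7.67e-05, 5.52e-05, 0.000123 and 0.000132, and adjusted p = 0.413, 0.26, 0.59, 0.59 and 0.26 with an estimated correlation. PDC5 had a lower response in the knockout by 4.84 on the log2 scale, against the direction of its list. Of 22 aminoacyl-tRNA synthetases 17 were higher and 1 lower, or 18 and 1 adjusted over the list alone (median 0.65, camera adjusted p = 5.52e-05, and adjusted p = 0.413 with an estimated correlation). Of 19 genes of the phosphate regulon (Pho4-type) 12 were higher and 2 lower, equally adjusted over the list alone (median 0.40, camera adjusted p = 0.0144, and adjusted p = 0.272 with an estimated correlation). The glucose-repressed genes had 28 of 40 members lower and 5 higher, or 29 and 6 adjusted over the list alone (median −0.82, camera adjusted p = 0.000245, and adjusted p = 0.413 with an estimated correlation). For the general stress response (Msn2/4-type) the interaction was not called (18 higher, 20 lower, median 0.00, camera adjusted p = 0.966).

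The other 8 lists called in the interaction each lost the call under at least 1 scaling or without 1 library. The response was lower in the knockout for 62 of 152 ribosome biogenesis genes (14 higher, or 61 and 12 adjusted over the list alone, median −0.21) and for 14 of 24 genes of the iron regulon (4 higher, or 15 and 4 adjusted over the list alone, median −0.52). It was lower for 18 of 37 genes for methionine and sulfate assimilation (8 higher, median −0.52) and 32 of 61 for tRNA modification and maturation (8 higher, median −0.25), equally adjusted over the list alone. The camera adjusted p values of these 4 lists were 0.00337, 0.0144, 0.0235 and 0.0321, and adjusted p = 0.778, 0.687, 0.59 and 0.645 with an estimated correlation. The response was higher for 16 of 27 ergosterol biosynthesis genes (5 lower, median 0.33), 12 of 18 translation elongation and termination factors (2 lower, median 0.55) and 20 of 37 heat shock factor and chaperone genes (8 lower, median 0.40), equally adjusted over the list alone. It was higher for 24 of 45 genes for cell wall integrity and cell wall (13 lower, or 28 and 13 adjusted over the list alone, median 0.67). The camera adjusted p values of these 4 were 0.0189, 0.0209, 0.0226 and 0.0274, and adjusted p = 0.59, 0.64, 0.64 and 0.778 with an estimated correlation. The calls other than methionine and sulfate assimilation and the cell wall ended with FPKM as deposited (adjusted p = 0.192 to 0.418) and with TPM (adjusted p = 0.117 to 0.18). Without treated wild-type library 2 the adjusted p of methionine and sulfate assimilation was 0.0636 and that of tRNA modification and maturation 0.0958, and the latter was 0.0656 without untreated wild-type library 1. With quantile normalisation that of cell wall integrity and cell wall was 0.0628, that of heat shock factor and chaperone genes 0.0879 and that of tRNA modification and maturation 0.0973.

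With hygromycin B present, knockout and wild-type cells differed widely. CTR1, the high-affinity copper transporter, was 25.9-fold higher in the knockout, at 998 ± 36.8 against 37.6 ± 2.98 normalised FPKM (SD, n = 2; log2 4.70 ± 0.10 SE, limma adjusted p = 5.34e-07). The HO gene for the mating-type endonuclease was 24.7-fold higher, CLN2, a G1 cyclin, 17.9-fold higher at 108 ± 4.59 against 5.13 ± 0.875, and AZR1 24.0-fold higher. CUP1-1 and CUP1-2 were lower by 124-fold in the knockout, at 163 ± 1.01 against 20360 ± 1710, with the same limit on reads shared between copies. SRL1 and CIS3 were 25.7-fold and 17.5-fold higher in the knockout.

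All 10 histone genes, 91 of 97 cytosolic ribosomal proteins (4 lower) and 38 of 40 proteasome genes (1 lower) were higher in the knockout with hygromycin B. All 22 aminoacyl-tRNA synthetases, 25 of 30 translation initiation factors (0 lower) and 18 of 21 genes of glycolysis and fermentation (2 lower) were higher too. These numbers were equal adjusted over the list alone. The 6 medians were 1.46, 0.94, 0.84, 0.78, 0.60 and 1.25, with camera adjusted p = 8.06e-05, 1.01e-12, 2.51e-09, 5.78e-07, 1.03e-05 and 8.06e-05, and adjusted p = 0.508, 0.576, 0.37, 0.37, 0.575 and 0.576 with an estimated correlation. HTB2 was at 1091 ± 28.3 against 138 ± 4.54 and RPS22B, a ribosomal protein gene, at 946 ± 13.5 against 118 ± 8.9. Of 29 genes of the unfolded protein response of the endoplasmic reticulum 21 were higher and 4 lower, of 27 ergosterol biosynthesis genes 20 and 4, and of 18 translation elongation and termination factors 15 and 3, equally adjusted over the list alone. Of 15 a-cell and haploid genes 11 were higher and 2 lower, or 12 and 2 adjusted over the list alone. The 4 medians were 0.68, 0.67, 0.81 and 1.21, with camera adjusted p = 0.000218, 0.000604, 0.00726 and 0.00131, and adjusted p = 0.37, 0.408, 0.576 and 0.37 with an estimated correlation. The call for elongation and termination factors ended with FPKM as deposited (adjusted p = 0.132).

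Of 40 glucose-repressed genes 30 were lower and 4 higher in the treated knockout than in treated wild type, equally adjusted over the list alone (median −0.89). In the general stress response (Msn2/4-type) 42 of 60 were lower and 9 higher, or 43 and 9 adjusted over the list alone (median −0.77). Of 37 genes for methionine and sulfate assimilation 23 were lower and 9 higher, equally adjusted over the list alone (median −0.45). Their camera adjusted p values were 7.43e-05, 0.000504 and 0.0161, and adjusted p = 0.408, 0.67 and 0.575 with an estimated correlation. HSP26 was at 44.5 ± 3.13 against 427 ± 5.68. Of 66 mitochondrial ribosomal proteins 37 were lower and 15 higher, equally adjusted over the list alone (median −0.29). Of 152 ribosome biogenesis genes 72 were lower and 21 higher, or 71 and 21 adjusted over the list alone (median −0.16). They had camera adjusted p = 0.0378 and 0.0424, and adjusted p = 0.778 and 0.819 with an estimated correlation. Both ended with FPKM as deposited (adjusted p = 0.34 and 0.762), with TPM (adjusted p = 0.0784 and 0.342) and without treated knockout library 2 (adjusted p = 0.0708 and 0.111). The first also ended without treated wild-type library 1 (adjusted p = 0.0731) and the second without treated wild-type library 2 (adjusted p = 0.165).

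**Figure D2:**
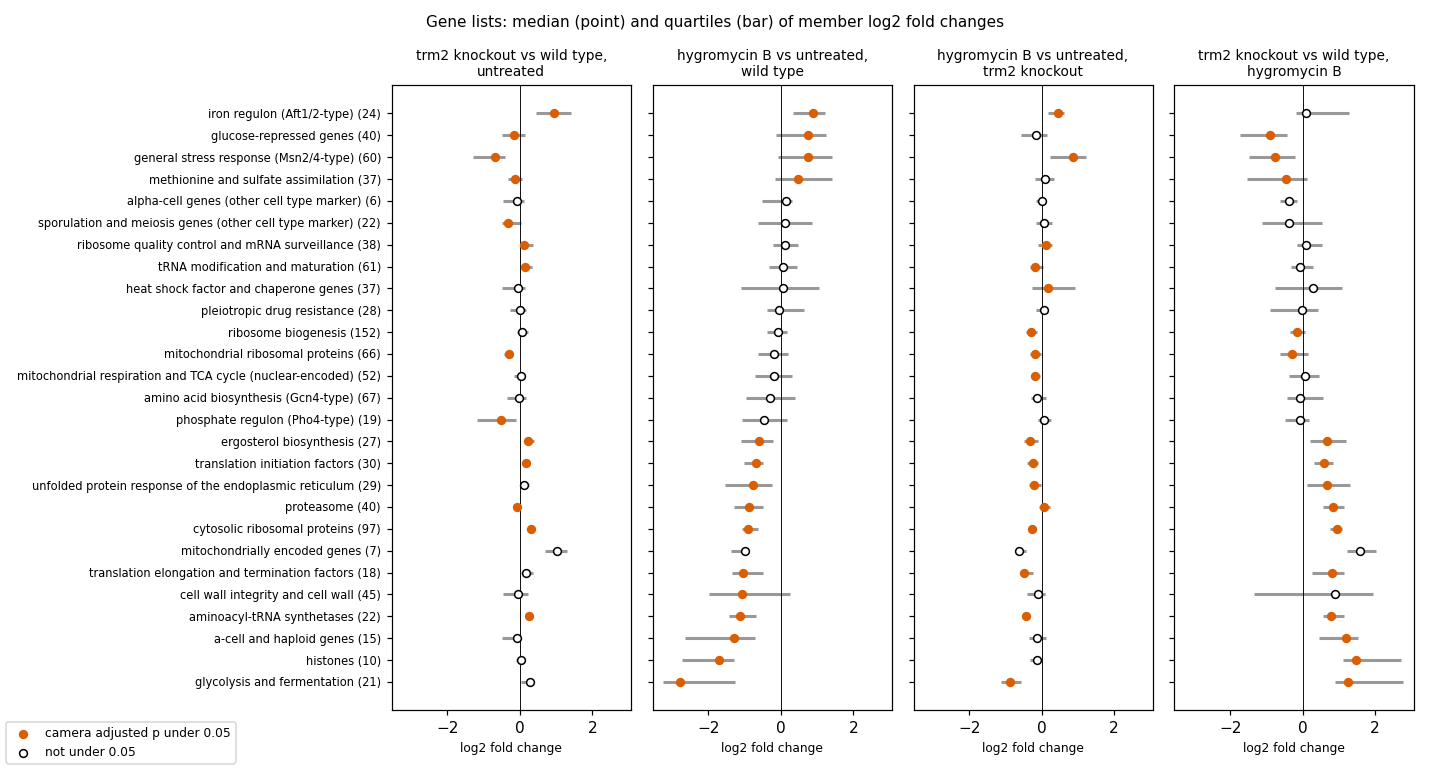
Median (point) and quartiles (bar) of the members' log2 fold changes for each of 27 gene lists in 4 comparisons, each between 2 groups of 2 libraries; filled points have a camera adjusted p under 0.05 at the preset correlation (with an estimated correlation 0 of the 27 lists have one in any comparison), and numbers in brackets are tested members. Median −2.78 for glycolysis and fermentation with hygromycin B in wild type is the farthest from 0; some small medians, such as the 0.15 of tRNA modification and maturation in untreated cells, change sign with FPKM as deposited.

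With hygromycin B 4976 genes passed between knockout and wild type, 2392 higher and 2584 lower in the knockout, and 1677 differed at least 2-fold, 787 higher and 890 lower. With FPKM as deposited the median of all genes was at −0.53, 2128 genes passed and 16.6% of them were higher, against 48.1% with the scale factors. With TPM the median was at −0.35 and 28.7% were higher. In the interaction the corresponding medians were −0.24 and −0.13, with 469 and 2238 genes passing and 30.1% and 38.9% of them higher, against 47.5% with the scale factors.

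Among lists that were not called, pleiotropic drug resistance had medians of 0.01 without drug (adjusted p = 0.933) and −0.06 with hygromycin B in wild type (adjusted p = 0.83), although SNQ2, a drug efflux pump, rose in the knockout from 113 ± 5.1 to 398 ± 9.86 normalised FPKM. Amino acid biosynthesis (Gcn4-type) had a median of −0.02 without drug (camera adjusted p = 0.0967) and −0.29 with hygromycin B in wild type (adjusted p = 0.2). Of 8 measured mitochondrially encoded genes 7 were tested, and 0 of them passed without drug (median 1.01, camera adjusted p = 0.535). With hygromycin B in wild type 1 fell and 0 rose, and in the treated knockout 2 were higher than in treated wild type and 0 lower. The RNA was selected with oligo-dT beads, and how well that captures these transcripts was not tested. The alpha-cell genes, markers of the other mating type, had a median of −0.09 without drug (camera adjusted p = 0.396).

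**Figure D3:**
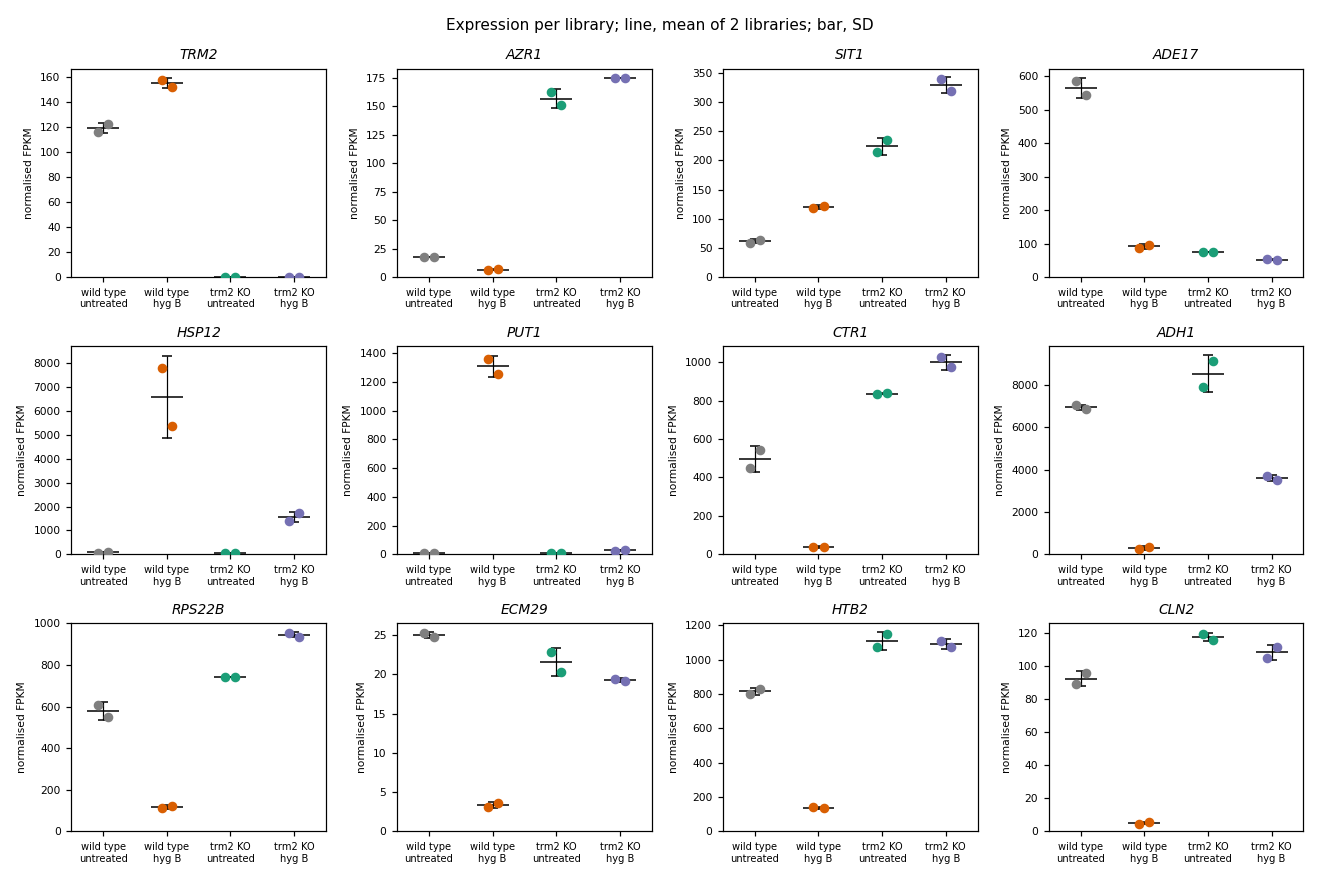
Normalised FPKM of 12 genes in each library (points, 2 per group), with the group mean (line) and SD (bar), on linear axes from 0. TRM2 is listed at 0 in the 4 knockout libraries, and CTR1, ADH1, RPS22B, ECM29, HTB2 and CLN2 are lowest in the treated wild-type group.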

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

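The interaction between genotype and hygromycin B was planned, and every test of an explanation in this part was chosen only after the result was seen. The response to hygromycin B differed between the genotypes for 4153 genes by limma's interaction term. SRL1 and CIS3, cell wall mannoproteins, had interaction log2 values of 4.65 and 4.37, LSO1 of 4.49, YHR073W-A of 5.40, and CUP1-1 and CUP1-2 of −6.18 each. Positive values stand for a more positive log2 change in the knockout, which can be a larger rise or a smaller fall.

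The interaction also passed for 4 genes listed at 0 in part of the libraries, given here by library. YGR027W-A, which lies inside a Ty element frame on the same strand, was at 260 and 238 normalised FPKM in treated wild type and listed at 0 in the other 6 libraries. YAR010C, a Ty element frame, was at 68.8 and 71.2 in treated wild type, at 0.0845 in untreated knockout library 2, and listed at 0 in the other 5. Ty elements have near-identical copies between which reads are divided, so these values are uncertain. YBR182C-A was listed at 0 in untreated wild type, at 89.2 and 61.1 in treated wild type, at 4.30 and 6.25 in the untreated knockout and at 3.34 and 5.29 in the treated knockout. YML100W-A was at 9.71 and 9.47 in untreated wild type, at 24.7 in treated knockout library 2, and listed at 0 in the other 5.

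The median interaction log2 of the lists called was 1.96 for glycolysis and fermentation, 1.34 for histones, 1.25 for a-cell and haploid genes and 1.02 for the proteasome. It was 0.67 for cell wall integrity and cell wall, 0.65 for aminoacyl-tRNA synthetases, 0.64 for cytosolic ribosomal proteins, 0.55 for translation elongation and termination factors and 0.53 for the unfolded protein response. The median was 0.41 for translation initiation factors, 0.40 for both heat shock factor and chaperone genes and the phosphate regulon, and 0.33 for ergosterol biosynthesis. Below 0 were the medians of glucose-repressed genes (−0.82), methionine and sulfate assimilation (−0.52), the iron regulon (−0.52), tRNA modification and maturation (−0.25) and ribosome biogenesis (−0.21). With an estimated correlation camera called 0 of the 27 lists for the interaction (lowest adjusted p = 0.26, with 4 lists at an unadjusted p under 0.05).

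The hygromycin B response was smaller in the trm2 knockout, with a median absolute log2 change of 0.236 against 0.652 in wild type. Ribosomal RNA that differs between libraries, as far as the features with ribosomal DNA names measure it, is argued against as the cause. The ratio of these medians was 0.365 with the ribosomal DNA share as a covariate against 0.362 without it. With FPKM as deposited the ratio was 0.495, which does not bear on this cause, because those values keep any effect of ribosomal RNA. A single factor that shrinks every gene's response in proportion, as a lower effective dose with a linear response might, is argued against by the general stress response, whose mean knockout response less 0.226 (the common slope, taken as fixed) times the wild-type one was 0.65 relative to all genes (95% interval from the spread between libraries 0.40 to 0.90, adjusted p = 0.0181 by Benjamini-Hochberg over 27 lists, of which 13 passed). A dose response that is not linear stays open. Geneticin in the knockout cultures, or another culture difference between the genotypes, cannot be told apart from the loss of TRM2, because the labels state Geneticin for 0 wild-type libraries.

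In wild type, hygromycin B raised the CUP1 copies and lowered the copper uptake genes CTR1, FRE1 and FRE7, whereas in the knockout the log2 changes were −0.41 for CUP1-1 and CUP1-2, 0.26 for CTR1, 0.13 for FRE1 and 0.23 for FRE7, and 0 of these 5 passed. The interaction passed for all 5, at −6.18 for both CUP1 copies, 3.93 for CTR1, 2.61 for FRE1 and 1.45 for FRE7. Before hygromycin B the knockout already differed from wild type in all 5. Those log2 differences were −0.78 for both CUP1 copies, 0.76 for CTR1, 1.37 for FRE1 and 0.51 for FRE7. A rise of CUP1 and a rise of RUF5, whose reads may be shared with it, cannot be told apart, because RUF5-1 and RUF5-2 on the other strand changed by 5.09 ± 0.27 (SE) in wild type and the strand setting was not given. More copper available to the treated wild-type cells may lower the uptake genes and raise CUP1, but SOD1, the only other copper-induced gene with a value here, changed by −0.76 ± 0.10 (SE). That explanation stays open, because 1 gene with other regulators does not decide it.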

How the results depend on the processing

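The ribosomal DNA covariate and the fit without zeros were chosen only after the results were seen, and the other alternatives were planned. With FPKM as deposited 163 genes passed for knockout against wild type without drug, 2550 with hygromycin B in wild type, 1.1e+02 in the knockout (82 higher, 23 lower), 2128 between genotypes in hygromycin B and 469 for the interaction. With TPM 1032 genes passed without drug, 1513 with hygromycin B in the knockout and 2238 for the interaction. The scale factors of 0.611 to 1.44, which FPKM as deposited lack, differed within groups as well. On the log2 scale they were −0.464 and 0.273 in untreated wild type and 0.517 and 0.522 in treated wild type. They were −0.71 and −0.078 in the untreated knockout and 0.214 and −0.185 in the treated knockout. Without scaling these shifts remain in the spread within groups, and how far that lowered the counts was not tested. With a minimum 2-fold change 225, 1885, 148, 1677 and 1302 genes passed, fewer by construction. Gene lists called without drug fell to 9 with FPKM as deposited and to 9 with quantile normalisation, the cause of which was not tested. With an estimated inter-gene correlation camera called 0 lists in each of the 5 comparisons, where 1, 2, 1, 3 and 4 of the 27 had an unadjusted p under 0.05. The phosphate regulon and the sporulation and meiosis genes had estimated correlations of −0.038 and −0.008, below the preset one. Without drug their camera adjusted p still went from 1.42e-06 to 0.135 and from 0.0492 to 0.433. For these lists that argues against a higher correlation as the cause. The repeat also had fewer degrees of freedom, the 4 of the residuals in place of a number set by the genes tested. The other called lists had estimates above the preset one, and for them the 2 changes were not tested apart. The correlation of the responses across genes, 0.488, was 0.454 with quantile normalisation, 0.395 with a pseudocount of 0.1, 0.543 with a pseudocount of 5, 0.523 among genes with a mean of at least 10 FPKM and 0.545 without zeros, and the cause was not tested.

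Leaving out each library in turn gave 1689 to 3243 genes without drug, 4696 to 5018 in wild type, 1466 to 3287 in the knockout, 4434 to 4931 between genotypes in hygromycin B and 3609 to 4313 for the interaction. The lists called were 9 to 16, 14 to 17, 15 to 17, 13 to 15 and 16 to 18, and the correlation was 0.437 to 0.488. The count without drug moved by over 1.5 times without untreated wild-type library 1 (1689) or 2 (1765) and without untreated knockout library 1 (1764, with 9 lists) or 2 (1781). That in the knockout did so without untreated knockout library 2 (1668) and without treated knockout library 1 (1742) or 2 (1466). A lone remaining library was taken to vary like the other groups. With the replicate number as a block 2712, 5078, 2806, 4993 and 4140 genes and 14, 15, 15, 14 and 18 lists passed. The block ended the calls of the proteasome with hygromycin B in the knockout (adjusted p = 0.0551) and of ribosome biogenesis between genotypes in hygromycin B (adjusted p = 0.0503). It also ended those of HTA1 and HTB1 without drug, RHO4 and RPS21A in the knockout and COX1 between genotypes in hygromycin B, and no other call of a list or named gene. Deviations of same-numbered libraries correlated at −0.232 to 0.256 between groups, and the sources used here name nothing that same-numbered libraries share. With the ribosomal DNA covariate 2446, 4931, 2563, 4768 and 4036 genes passed, and without zeros 2787, 5027, 2810, 4924 and 4122. That covariate ended the calls of sporulation and meiosis genes without drug (adjusted p = 0.0527), the proteasome in the knockout (0.0759), and ribosome biogenesis (0.136) and mitochondrial ribosomal proteins (0.0574) between genotypes in hygromycin B, and the cause was not tested.

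Of the values of named genes under the alternatives, 11327 kept their direction and side of the threshold, 605 were weaker, 3 stronger and 24 turned. Without drug, RHO4 (−0.025), GCD1 (−0.066), TIF1 (−0.026) and HIS3 (−0.253) turned with FPKM as deposited, HIS3 with TPM (−0.184) and without untreated wild-type library 1 (−0.005) or untreated knockout library 2 (−0.062, against 0.13 without library 1), and RPS21A with quantile normalisation (−0.047). In the knockout with hygromycin B and FPKM as deposited, RHO4 (0.219), RPS21A (0.155), HIS3 (0.194), RPS19B (0.001), OST1 (0.016), FPR2 (0.106), RSM22 (0.034), HHT2 (0.084), HHO1 (0.062), FUS1 (0.004) and FAR1 (0.091) turned. With TPM this held for RHO4 (0.116), RPS21A (0.050), HIS3 (0.091) and FPR2 (0.001), and with quantile normalisation for RPS21A (0.059). With FPKM as deposited and with TPM the median of all genes was at −0.26 and −0.19 without drug and at 0.36 and 0.26 in the knockout, and each gene that turned there lay on the side of that median where it had lain of 0. For the other turned values the cause was not tested. Read depth was unknown, so no limit from counting is given for low genes.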

Other observations

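The gene groups in this part, and every test of an explanation, were chosen only after the results were seen. Genes under nitrogen catabolite repression, which are switched on when good nitrogen sources are scarce, rose in wild type with hygromycin B, 19 of 21 of them, with 1 lower and a median log2 change of 1.85. The ammonium transporter MEP2 rose 22.6-fold, from 32 ± 0.532 to 745 ± 29.7 normalised FPKM (SD, n = 2), the general amino acid permease GAP1 18.3-fold and DAL3, an enzyme of allantoin use, 32.9-fold. In the knockout 7 of the 21 rose and 2 fell, with a median of 0.15 (0.44 with FPKM as deposited). The interaction passed for 19 of the 21, each with a lower response in the knockout (median −1.88).

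Purine and one-carbon genes of the Bas1 type were lower in the knockout without drug, all 14 of them, with a median of −1.48, and hygromycin B lowered 10 and raised 2 of the 14 in wild type (median −1.25, or −0.64 with FPKM as deposited). In the knockout the drug raised 6 and lowered 6 (median 0.06, or 0.46 with FPKM as deposited and 0.36 with TPM). With hygromycin B present 2 were higher and 4 lower in the knockout than in wild type (median −0.15, or −0.66 with FPKM as deposited and −0.47 with TPM). The interaction was higher for all 14 (median 1.46). SHM2, the cytosolic serine hydroxymethyltransferase, was at 633 ± 2.29 normalised FPKM in untreated wild type, 241 ± 25.8 in treated wild type, 141 ± 13.4 in the untreated knockout and 205 ± 10.4 in the treated knockout. Cell cycle genes were lower in treated wild type. All 12 G1/S genes and all 8 mitotic genes fell there, with medians of −2.53 and −1.74, RNR1 from 93.4 ± 4.17 to 8.66 ± 1.1 and CLB2 from 55.1 ± 1.26 to 8.62 ± 0.654. In the knockout the medians with hygromycin B were 0.09 for G1/S and −0.07 for mitotic genes, against 0.49 and 0.33 with FPKM as deposited and 0.39 and 0.22 with TPM, and the interaction passed for all 12 and all 8.

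Multidrug genes of the Yrr1 type were higher in the knockout without drug (10 of 11 higher, 1 lower, median 1.55) and with hygromycin B (9 higher, 2 lower, median 1.53), among them AZR1 and SNQ2. Library scaling is argued against as the cause, since the lowest median over 4 other fits was 1.25 without drug and 1.04 with hygromycin B. A mislabelled library is argued against too, since TRM2 went against the label in 0 libraries. Geneticin or a second mutation in the knockout strain could raise these genes as well as the loss of TRM2 could, and these cannot be told apart, because 0 wild-type libraries are stated to have had Geneticin and no second knockout strain was analysed here.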
